A study of Mus musculus with 2 samples.

How the data were processed

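Nuclei from mouse retinas of the oxygen-induced retinopathy model at postnatal day 17 were measured as 1 RNA sample and 1 open chromatin (ATAC) sample, which are joint libraries of the same nuclei. The labels give no room-air control, no replicate and no number of animals. All comparisons therefore lie within 1 preparation, and no test between samples was possible.

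The submitters' processing notes name Cell Ranger ARC 2.0.2 and the genome build mm10. The deposited matrix held whole-number counts, UMIs for 32285 genes and counts in 72371 peaks, for the same 13402 called barcodes. Per the file headers, the fragment table came from the same version and the mm10 reference, and gave counts of read pairs behind each unique fragment for all barcodes. The deposited feature table gave start and end positions in bases, in another unit than counts. Those positions are printed here as stored. How barcodes were filtered beyond the calling of nuclei is not stated.

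Nuclei were kept with 500 to 25000 UMIs, at least 250 genes, at most 10% mitochondrial UMIs and 1000 to 100000 counts in peaks. Of the called barcodes, 6854 passed (51.1%), and 5671 fell under the limit on peak counts. Scrublet in scanpy 1.11.5, with an expected share of 8%, called 2 doublets (0.0292%). A share under 0.5% was taken to mean that the caller had not worked on these nuclei. The 2 calls were removed, and 6852 nuclei remained, with a median of 1959 UMIs and 3774 peak counts.

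Each UMI was assigned at random, with a probability of 0.5, to a training or a held-out part. Clusters and their names came from the training part, which held 11081498 UMIs. Every level printed came from the held-out part, which held 11080539 UMIs, so that clustering on a gene could not by itself make its difference. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method (leidenalg 0.10.2) at a resolution of 1.0. Müller-like nuclei were clustered again with 1000 genes, 15 components and a resolution of 0.5, leaving out the genes of every list and marker set. Peak counts were clustered apart from RNA by latent semantic indexing with 30 components (scikit-learn 1.9.0).

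A cluster took the name of 1 of 16 marker sets fixed before the data were examined. At least 3 of its markers had to be detected, with no other set leading its top 10 genes or detected in a larger share. Details of this rule were set after the first clusters were seen. A marker counted as detected with at least 10 UMIs, a UMI in at least 5% of the cluster's nuclei, and a CPM at least 2 times that of clusters of other classes, after adding 10 CPM to both. Names are written with "-like", since no other evidence of identity was used.

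Levels are UMI counts scaled to equal totals (CPM) over summed nuclei, with exact Poisson intervals at 95%. Shares of nuclei have exact Clopper-Pearson intervals, and ratios of CPM have exact conditional binomial intervals. For each of 25 gene lists fixed before the data were examined, the median log2 ratio was taken over members with at least 20 UMIs in the compared pools. Its interval came from 1000 Poisson draws, and its percentile from 10000 random lists matched on expression. List medians and ranks add 1 count to each pool. So do the printed ratios of the 20 leading Müller genes, of leading peaks and of single promoters in Müller subclusters. Other single ratios do not, unless stated, and intervals of single ratios add no count. All intervals cover counting error only, not differences between animals.

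Promoter counts were those of whole peaks that reached within 1000 bases of a gene's transcription start interval in the feature table. They can therefore include signal outside that window. Gene bodies came from RefSeq genes on GRCm38.p6, the assembly behind mm10, which matched 26316 of 32272 genes with a start interval (81.5%). Fragments were read once for depth, length, the profile around 21733 start sites and the Y chromosome below 4 Mb. The rules for sex were set after the data were seen. Female nuclei had at least 2 Xist UMIs and no Y fragment, male nuclei had no Xist UMI and at least 1 Y fragment, and nuclei counted for both had at least 2 of each.

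Genes were named by a rule written before the data were examined. Vegfa, Gfap, Glul and Rlbp1 are always named. Up to 4 members of each list with the largest absolute log2 ratio could be named in each comparison. For Müller-like nuclei, the 20 genes outside the marker sets with the largest ratio to any other class of at least 100 nuclei were named, given at least 50 UMIs. For each Müller subcluster of at least 50 nuclei, the 8 genes with the largest ratio to the other Müller-like nuclei were named, given at least 30 UMIs. The account of subcluster 4, which holds 36 nuclei, and the comparisons of subcluster 1 with 2 and of 4 with 1 and 2 together were chosen after the data were seen. So were the other genes named for the astrocyte-like, RPE-like and smallest Müller groups, and in the closing tests.

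The ratios were tested on simulated data with 200 changed genes at the depths of 2 of the comparisons. Between 93.6% and 98.0% of intervals held the simulated ratio. Simulated log2 ratios of -1 and -2 were read as -0.81 and -1.75 for Müller-like against other nuclei, so low ratios in that comparison are underestimates in size. In a simulated class without subclusters, the 8 top genes had a median log2 ratio of 0.15 on held-out UMIs and of 1.19 when the same UMIs were used for both steps.

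Alternatives covered looser and stricter filters, doublet handling, resolution, the number of genes and components, the splitting of UMIs, list minimums, the source and set of subclusters, gene bodies in place of promoters, and 20 or 50 ATAC components. Alternatives added after seeing the data were no limit on peak counts, removal of the highest 8% of Scrublet scores, removal of nuclei with signals of both sexes, each sex alone, and subclusters of at least 20 nuclei. The list medians without the members that also mark Müller-like nuclei were added then too. Motif searches in peaks were planned but not run, since no genome sequence was at hand. List symbols Ctgf, Cyr61 and Ero1a matched no row of the matrix, and 40 symbols named more than 1 row, of which the one with more UMIs kept the symbol. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.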

Results

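Oxygen-induced retinopathy is a mouse model in which pups kept in high oxygen lose retinal capillaries and, back in room air, grow abnormal vessels from a retina short of oxygen. Retinas were collected at postnatal day 17, when that growth is near its height. The RNA sample and the open chromatin (ATAC) sample came from the same nuclei, 1 sample of each kind, without a room-air control. The RNA sample held 37860626 UMIs in 13402 called barcodes. The ATAC sample held 115785662 unique fragments, of which 84561817 (73.0%) lay in the called barcodes, and 57493633 counts in peaks. The 6852 kept nuclei had a median of 1959 UMIs, 1202.5 genes and 4042.5 fragments. With no replicate there was no test, and intervals are given at 95% and cover counting error only.

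The first question was which retinal cells the nuclei came from. Rod-like nuclei made up 81.0% of the kept nuclei (5548; exact interval 80.0 to 81.9%). Bipolar-like nuclei, the interneurons that receive photoreceptor input, made up 8.16% (559; 7.52 to 8.83%), and cone-like nuclei 3.27% (224; 2.86 to 3.72%). Müller-like nuclei, from the radial glia that span the retina, made up 4.51% (309; 4.03 to 5.03%). Nuclei like microglia or macrophages made up 1.12% (77; 0.888 to 1.40%). Nuclei named by transcripts of the retinal pigment epithelium (RPE) made up 1.59% (109; 1.31 to 1.92%), but their rod markers summed to 22352 CPM, beside 25604 in rod-like nuclei, and their RPE markers to 5565 CPM. That class held 18 nuclei under stricter filters, 20 at a lower resolution, 21 without the highest 8% of Scrublet scores and 31 with all UMIs. Astrocyte-like nuclei (15, 0.219%) and endothelial-like nuclei (11, 0.161%) were rare. No cluster took the name of amacrine, ganglion or horizontal cells, but nuclei were named by cluster and single nuclei of these classes were not searched for. Across all 13402 barcodes, the ganglion cell factor Pou4f2 had 0 UMIs. Gad1, the enzyme that makes GABA in amacrine cells, had UMIs in 22 barcodes and at least 3 UMIs in 6 of them, and Gad2 had UMIs in 59. Not all members of the amacrine set were rare. Slc6a9 had UMIs in 1773 barcodes, with at least 3 in 104 of them, and Pax6, also high in Müller-like nuclei, had UMIs in 578. The ganglion marker Rbpms was seen in 140 barcodes (206 UMIs) and the horizontal marker Onecut2 in 167 (212 UMIs). Over the alternatives, the Müller-like share was lowest, 2.97%, without a limit on peak counts and highest, 6.86%, in male nuclei alone. The share is raised by construction in nuclei of either sex, so the second value is not a sex difference. A female or male sex was found for 138 and 64 of 309 Müller-like nuclei but for 1466 and 702 of 5548 rod-like nuclei.

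A second question, which the model raises, was which cells carry the transcripts of vessel growth signals and their receptors. Vegfa (ENSMUSG00000023951, chromosome 17, start interval 46031355 to 46032369 on mm10), the main growth factor for new vessels in this model, was at 452 CPM in Müller-like nuclei (412 to 494, 483 UMIs). It was at 22.0 CPM in all other nuclei, a log2 ratio of 4.36 (4.13 to 4.60). Astrocyte-like nuclei had 226 CPM (120 to 386), bipolar-like nuclei 48.9 and rod-like nuclei 11.2 CPM (8.84 to 14.0). A Vegfa UMI was seen in 64.1% of Müller-like nuclei, which had a median of 5611 UMIs, and in 1.35% of rod-like nuclei, which had a median of 1717.

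The VEGF receptors Flt1 (ENSMUSG00000029648, chromosome 5, 147725987 to 147726011) and Kdr (ENSMUSG00000062960, chromosome 5, 75978457 to 75978458) were highest in endothelial-like nuclei, which they helped to name. Flt1 was at 3240 CPM there (2707 to 3847) and Kdr at 922 CPM (649 to 1271). Müller-like nuclei followed with 1135 CPM of Flt1 (1072 to 1201) and 516 CPM of Kdr (474 to 561), against 7.71 and 6.98 CPM in rod-like nuclei. The co-receptor Nrp1 was at 108 CPM in Müller-like nuclei, 195 in microglia-like and 623 in endothelial-like nuclei.

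**Figure D1:**
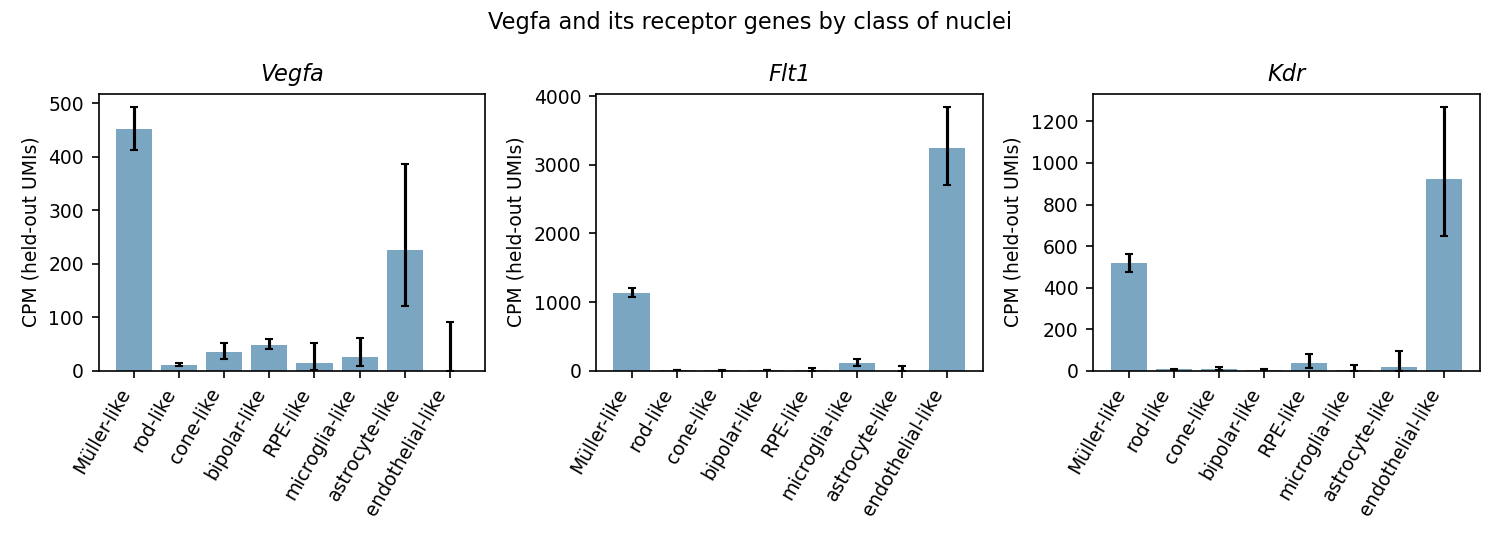
Bars show held-out UMIs of Vegfa, Flt1 and Kdr in CPM (counts scaled to equal UMI totals) in each of the 8 named classes, with exact Poisson intervals at 95%. Vegfa was highest in Müller-like nuclei at 452 CPM, and Flt1 and Kdr were highest in endothelial-like nuclei, with Müller-like nuclei next.

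Müller-like nuclei were then compared with all other nuclei over the fixed gene lists. The Müller-like pool, here and for Vegfa and its receptors above, included subclusters 3 and 5, described below. Their rod markers summed to 17846 and 11705 CPM, and they gave 277145 and 135245 of the 1069313 held-out UMIs. Levels and ratios of the pool may therefore differ from those of Müller cells alone. The list medians of glial and progenitor genes were among the highest. In the glial homeostasis list, 10 of 15 measured members were at least 2 times higher and the median log2 ratio was 3.12 (2.71 to 3.53). Among them were the potassium channel Kcnj10 (6.86), the carbonic anhydrase Car14 (5.82), the water channel Aqp4 (5.47) and the glutamate transporter Slc1a3 (5.44). Of those members, 5 also name the class, and the median without them was 1.35 (0.86 to 1.64). The progenitor list, transcription factors and Notch genes of retinal progenitors, had a median of 2.85 (2.58 to 3.55), with 14 of 17 members at least 2 times higher. Its leading members were Pax6 (6.06), Hes1 (5.66), Sox2 (5.65) and Sox9 (5.21). VEGF receptors had a median of 3.45 (3.09 to 3.83), with Flt1 at 5.65 and Kdr at 5.63.

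Glul (ENSMUSG00000026473, chromosome 1, 153899943 to 153900585), which makes glutamine from glutamate, was at 1617 CPM in Müller-like nuclei (1542 to 1695) and 29.1 CPM in rod-like nuclei. Rlbp1 (ENSMUSG00000039194, chromosome 7, 79386958 to 79387048), which binds retinaldehyde in the visual cycle, was at 708 CPM (658 to 760) and 15.3 CPM. Both are among the genes that name the class. The retinoid list had a median of 1.14 (0.71 to 1.57), led by Aldh1a1 (5.72), and without Rlbp1 the median was -0.25 (-1.12 to 0.59). Gfap (ENSMUSG00000020932, chromosome 11, 102897130 to 102897200), the intermediate filament of reactive glia, was at 21.5 CPM in Müller-like nuclei (13.6 to 32.3). It was at 2481 CPM in astrocyte-like nuclei (2091 to 2923) and at 2.18 CPM in rod-like nuclei. The gliosis list had a median of 1.34 (0.81 to 2.11), with 9 of 17 members at least 2 times higher, among them the oncostatin M receptor Osmr (5.55), the ferroxidase Cp (4.46), Vim (3.72) and Cd44 (3.65).

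Secreted angiogenic factors had a median of 1.06 (0.62 to 1.40). The peptide Adm (4.81), Vegfa, the ligand Apln (3.86) and Tgfb2 (3.13) were among the 10 of 17 members at least 2 times higher, and 5 were at least 2 times lower. That median was not stable. It was 2.52 with 3000 genes and 20 components, 2.13 at a lower resolution, 0.59 with all UMIs and 0.23 with the parts of the split exchanged. In these settings the median moved with the size of the endothelial-like class, which held 11 nuclei beside 309 Müller-like ones in the reported run. With 3000 genes and at the lower resolution no cluster was endothelial-like, and Müller-like nuclei numbered 326 and 320. With all UMIs and with the parts exchanged, 17 nuclei were endothelial-like. Under looser filters 22 nuclei were endothelial-like, but the median stayed within its reported interval, so the pattern did not hold in every setting. Whether endothelial nuclei had joined the Müller-like class was not traced. The median was 0.19 in female nuclei and -0.35 (-1.15 to 0.48) in male nuclei, where 6 members were measured. Hypoxia targets had a median of 0.43 (0.31 to 0.69), with 9 of 25 members at least 2 times higher, led by Adm, Vegfa, Bhlhe40 (4.35) and Egln3 (3.23). Glycolysis genes had a median of 0.06 (-0.11 to 0.21), with Aldoc at 2.22 and Ldhb at 1.98.

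Among regulators, immediate-early genes of the AP-1 group had a median of 2.36 (2.10 to 2.47), with Fosb at 4.27 and Fos at 3.76. The NFI factors, which act in late progenitors and glia, had a median of 2.37 (2.22 to 2.49), with Nfib at 3.21. The Notch pathway (1.91, 1.48 to 2.46) was led by Hes1 and Notch2 (3.86). The Wnt and Norrin pathway (1.88, 1.32 to 2.22) was led by Tcf7l2 (3.42) and the Norrin co-receptor Tspan12 (3.32). The YAP and TEAD list, which holds these factors and their targets (1.43, 1.16 to 1.83), was led by the matricellular gene Ccn1 (5.34). The TGF-beta and BMP pathway (0.63, 0.36 to 0.99) included the BMP receptor Bmpr1b (5.81) and Id1 (4.54).

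Extracellular matrix genes had a median of 1.30 (0.97 to 1.61), with the laminin Lama1 at 6.06 and Col4a5 at 4.27. Cholesterol genes had 1.05 (0.32 to 1.30), with the lipid carrier Apoe, also a class marker, at 3.15, and 1.00 without it. Medians of the inflammatory list (0.96, 0.58 to 1.23; the alarmin Il33 at 5.86), oxidative stress list (0.65, 0.35 to 0.98; the cystine transporter Slc7a11 at 4.17) and JAK-STAT list (0.47, 0.19 to 0.84; Oasl2 at 4.41) were lower. Blood-retina barrier genes had 0.96, with an interval of -0.10 to 2.01, and the unfolded protein response had 0.23 (-0.15 to 0.51). Medians below 0 were those of the cell cycle (-0.16, -0.95 to 0.13), activated microglia (-0.73, -1.71 to 0.13), endothelial tip and tuft cells (-0.89, -1.66 to -0.32) and homeostatic microglia (-1.83, -2.23 to -1.14).

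**Figure D2:**
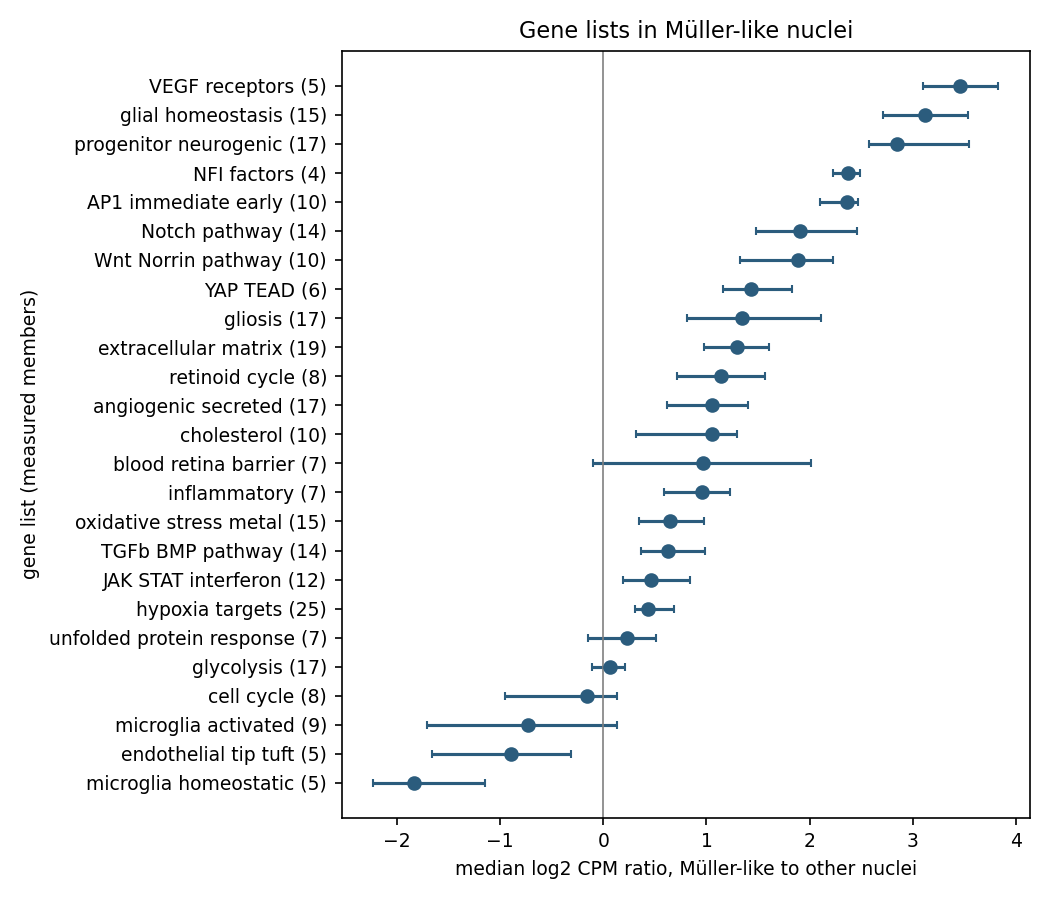
Points show the median log2 ratio of CPM in Müller-like nuclei to all other nuclei for each gene list, and bars show 95% intervals from 1000 Poisson draws. VEGF receptors (3.45), glial homeostasis (3.12) and progenitor genes (2.85) lie highest, and homeostatic microglia (-1.83) lowest.

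The 20 genes outside the marker sets that set Müller-like nuclei furthest above any other class of at least 100 nuclei were led by Adamts19, a secreted metalloprotease. It was at 970 CPM, with a log2 ratio of 7.48 to the next class. Slc13a5, a citrate transporter (6.88), Folh1 (6.53), Adgrg6 (6.38) and Col9a1, a collagen chain (6.32, at 2258 CPM), followed. The others were Bves, Prex2, Adamts12, Qrfpr, Cd9, Egfr, Greb1, Frzb, Spc25, Acot11, Pdzrn3, Prr5l, Nkd1, Fbn2 and Bmp3, with ratios between 5.84 and 6.31. Egfr, the epidermal growth factor receptor, was at 168 CPM and Cd9 at 691 CPM.

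The series title asks how Müller cells differ from each other. The Müller-like nuclei fell into 6 subclusters of 128, 71, 50, 36, 18 and 6 nuclei. Among the 3 of at least 50 nuclei, subcluster 1 was highest and subcluster 3 lowest for gliosis, hypoxia targets and glial homeostasis. Gliosis genes summed to 4150 CPM in subcluster 1 and 1555 in subcluster 3, a log2 ratio of 1.42 (1.26 to 1.58), with Cp at 1.79, Vim at 716 against 253 CPM and Fgf2 at -1.88. Glial homeostasis genes summed to 8503 and 3446 CPM, a ratio of 1.30 (1.20 to 1.41), with Aqp4 at 2.18, Slc1a3 at 1.84 and Glul at 1.76. Hypoxia targets summed to 4340 and 3143 CPM, a ratio of 0.47 (0.34 to 0.59), with Bhlhe40 at 2.84, Vegfa at 1.36 and Ndrg1 at -1.92.

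Subcluster 3 was led by the cone opsins Opn1sw (4.06) and Opn1mw (2.96). Its rod markers summed to 17846 CPM, against 1221 CPM in subcluster 1, and its Müller markers to 4640 against 15389 CPM. Signals of both sexes, from Xist RNA and Y fragments, were seen in 34.0% of its nuclei and in 0.781% of those of subcluster 1. Depth raises such calls, and the medians were 10315 UMIs and 26666 fragments in subcluster 3 against 4540.5 and 8557.5 in subcluster 1. The gap between these percents is therefore not a measure of mixing alone. Without subcluster 3, the ratios were 0.50 for gliosis, 0.13 for hypoxia targets and 0.30 for glial homeostasis. Removal of nuclei with both signals gave 0.83 for gliosis, 0.21 for hypoxia targets and 1.27 for glial homeostasis, the last within its reported interval, and removal of the highest 8% of Scrublet scores gave 0.25, 0.0047 and 0.38. Subcluster 5 was led by Car10 (8.35) and included the bipolar marker Isl1, with bipolar markers at 4828 CPM.

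Subclusters 1 and 2 differed less. Subcluster 1 was led by the adhesion molecule Vcam1 (2.14, 1.48 to 2.81), the EGFR inhibitor Errfi1 and the Wnt antagonist Frzb, and subcluster 2 by the calcium pump Atp2b2 (1.37), Dhx32 and Zhx2. Rod markers summed to 7405 CPM in subcluster 2 and 1221 in subcluster 1, their promoters to 462 and 169 CPM of peak counts, and 11.3% and 0.781% of nuclei held signals of both sexes. Median fragments were 12683 and 8557.5, and the greater depth of subcluster 2 also raises such signals. In subcluster 1 against 2, list medians were 0.75 for the retinoid cycle (Aldh1a1 at 1.04) and 0.69 for extracellular matrix (Lama1 at 1.02). They were 0.49 for AP-1 genes and 0.17 for gliosis (-0.17 to 0.53), where 4 of 6 members had intervals spanning 0. Cp made up 2842 of the 4150 CPM of gliosis genes in subcluster 1 and 1728 of 2939 in subcluster 2.

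**Figure D3:**
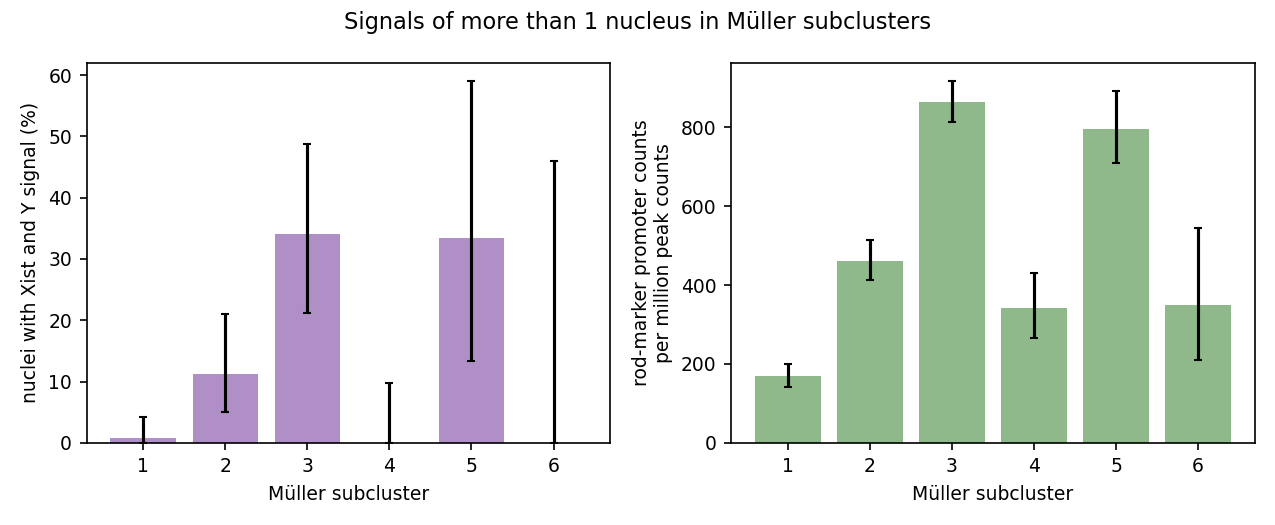
Bars show, for Müller subclusters 1 to 6, the percent of nuclei with both Xist UMIs and Y fragments and the counts in promoters of rod markers in CPM of peak counts. Subclusters 3 and 5 stand highest in both, at 34.0 and 33.3% and at 864 and 796 CPM. Their nuclei were also the deepest, with medians of 26666 and 18638.5 fragments, which raises the first percent.

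Subcluster 4, with 36 nuclei under the preset size, had higher reactive and hypoxia transcripts than subclusters 1 and 2. Its leading genes were S100a6, a calcium-binding protein (4.92, 4.38 to 5.48), the acute-phase gene Lcn2 (4.49), Cdh13 (4.35), the noncoding RNA Neat1 (4.12), Vav3, the metallothionein Mt2 (3.49), Inpp5f and Dclk1, each against all other Müller-like nuclei. Against subclusters 1 and 2, the gliosis list had a median of 1.19 (0.99 to 1.68), with 6 of 10 members at least 2 times higher and 0 at least 2 times lower. Gfap was at 161 CPM against 7.53 (16 and 4 UMIs, 4.41, 2.78 to 6.45), Lcn2 at 4.15, A2m at 3.28 and Osmr at 1.87. Hypoxia targets had a median of 0.94 (0.73 to 1.28), with 9 of 19 at least 2 times higher, among them Ankrd37 (2.54), Adm (2.41), Ero1l (2.30) and the glucose transporter Slc2a1 (1.73). Glycolysis genes had 0.94 (0.71 to 1.19), with Gpi1 at 2.02, Pgam1 at 2.01, Pgk1 at 1.42 and Aldoc at -1.52. The hypoxia and glycolysis lists share Hk2, Aldoa, Pgk1, Eno1 and Ldha, so their medians are not separate readings. Vegfa was at 983 against 563 CPM, a log2 ratio of 0.80 (0.46 to 1.14).

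Other lists were higher in subcluster 4 by less, such as JAK-STAT (0.83, 0.30 to 1.26) and AP-1 (0.63, 0.35 to 0.84, with Egr1 at 0.84 and Fos at 0.80). In the JAK-STAT list B2m was at 1.62, but 7 of 9 measured members had intervals spanning 0. Glial homeostasis had a median of -0.33 (-0.81 to -0.17), with Glul at 903 against 2438 CPM (-1.43, -1.76 to -1.12), Car2 at -1.97 and the bicarbonate transporter Slc4a4 at 2.41. Its Müller markers summed to 7774 CPM, against 15389 and 11876 in subclusters 1 and 2, and its rod markers to 4875 CPM. Signals of both sexes were seen in 0 of its 36 nuclei, at a low median of 5175 fragments. The retinoid list had -0.64 (-0.98 to -0.35), with Aldh1a1 at -4.60 (-9.91 to -2.09; 1 and 129 UMIs) and Rlbp1 at 572 against 1008 CPM. Flt1 (-0.49) and Kdr (-0.56) were lower. Under 11 other settings of the RNA clusters, a matching subcluster of 22 to 43 nuclei was found. Glial homeostasis genes there were lower than in other Müller-like nuclei, except with 3000 genes and 20 components, where the summed log2 ratio was 0.12. At the lower resolution, 25 of the 36 nuclei merged with others into a group of 154, where that summed ratio was 1.49. With subclusters from chromatin, all 36 merged into a group of 287.

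**Figure D4:**
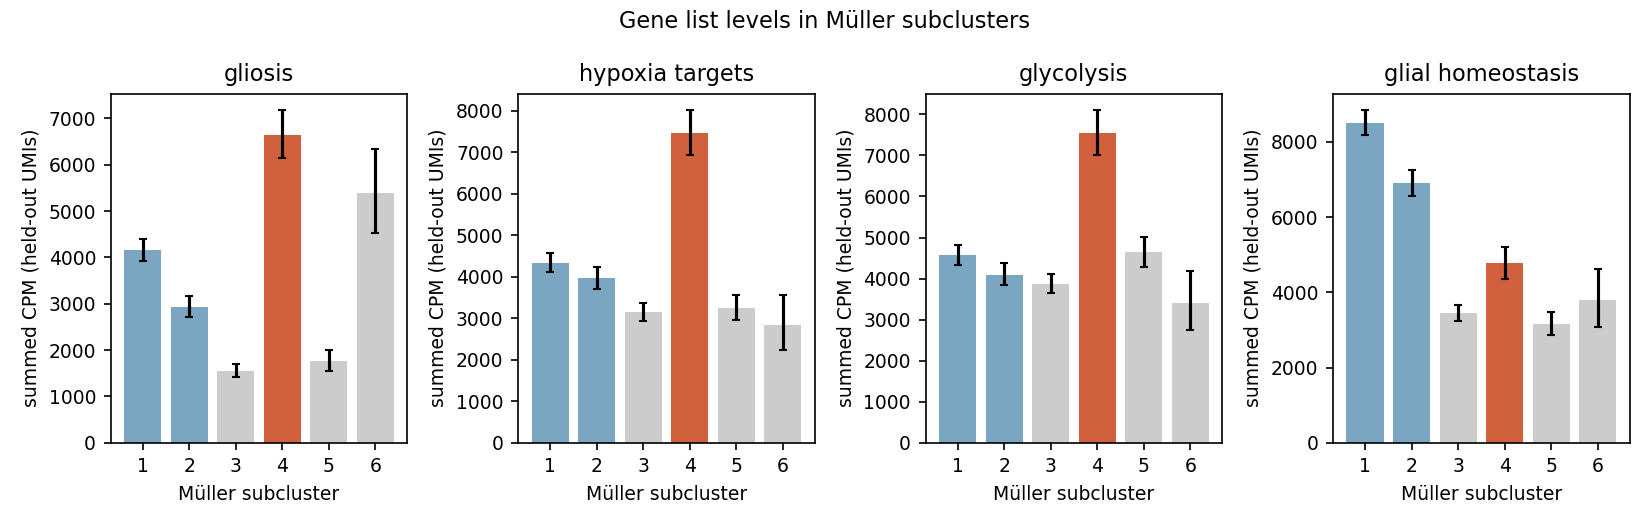
Bars show the summed CPM of gliosis, hypoxia target, glycolysis and glial homeostasis genes in Müller subclusters 1 to 6, with exact Poisson intervals at 95%; blue marks subclusters 1 and 2, orange subcluster 4 and grey subclusters 3, 5 and 6. Subcluster 4 is highest for gliosis (6651 CPM), hypoxia targets (7463) and glycolysis (7544), and subcluster 1 for glial homeostasis (8503).

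A further question was whether open chromatin in the same nuclei followed the RNA classes. Promoters of class markers had a median log2 ratio of 1.34 (1.15 to 1.45) in their own class over 44 markers. All 9 Müller markers measured were above 0, with a median of 1.51 (1.22 to 1.76), as were 11 of 11 rod, 9 of 9 cone and 10 of 10 bipolar markers. RPE markers had 0.18 (-0.53 to 0.64). Peaks counted for the Gfap promoter were at 22.8 CPM in Müller-like nuclei and 2.58 in the others, a log2 ratio of 3.15 (2.70 to 3.59). These are whole peaks that reach the promoter window. Within 1000 bases of the start lay 17 fragments of Müller-like, 62 of rod-like and 14 of bipolar-like nuclei. The ratio therefore does not measure opening within that window alone. The Gfap RNA ratio in Müller-like nuclei was 0.35 (-0.35 to 0.98), with 143 of the 169 Gfap UMIs of the other nuclei in the 15 astrocyte-like nuclei. The Vegfa promoter had a ratio of 0.57 (0.38 to 0.76) beside an RNA ratio of 4.36, and Glul 0.26 (0.08 to 0.44). Promoters of Sox9 (3.39), Rlbp1 (3.06), Kdr (2.20) and Aqp4 (1.48) were more open in Müller-like nuclei. Of the 20 leading Müller genes, 16 had a measured promoter, and 16 of 16 had a ratio above 0, with a median of 2.77.

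Clusters from peak counts alone placed 93.3% of nuclei (92.6 to 93.8%) in a cluster whose commonest RNA class was their own, and 65.8% (63.2 to 68.4%) of nuclei other than rod-like ones. That held for 90.3% of Müller-like, 91.2% of bipolar-like and 89.6% of microglia-like nuclei. No cone-like nucleus had a cone cluster to fall in, and 216 of 224 lay in rod clusters, as did 107 of 109 RPE-like nuclei. Among Müller-like nuclei, 128 of 128 of subcluster 1 and 33 of 36 of subcluster 4 lay in the Müller chromatin cluster, but 32 of 50 of subcluster 3. That cluster also held 14 of the 15 astrocyte-like nuclei, so it does not separate Müller-like from astrocyte-like chromatin. Across 12941 genes, which are not independent replicates, RNA and promoter ratios of Müller-like to other nuclei had a Spearman correlation of 0.436. The peak that set Müller-like nuclei furthest apart lay on chromosome 18 at 58778589 to 58779477, with 106 counts against 5 (7.71, 6.69 to 9.61), 163 bases from the start of Gm50227. For bipolar-like nuclei it lay in Lsamp (chromosome 16, 40877975 to 40878811, 6.36) and for rod-like nuclei in Thrb (chromosome 14, 17760848 to 17761545, 3.41, 55 against 1 counts, 1.85 to 9.72). For cone-like nuclei it lay 90546 bases from Capza3 (chromosome 6, 140132104 to 140132983, 4.15). For RPE-like nuclei it lay 598 bases from Gm10800 (chromosome 2, 98666297 to 98666702, 1.31), with 130 counts against 3328. Of peaks with at least 50 counts in the class, 0 of 2976 were 4-fold higher in RPE-like nuclei, so that peak did not mark them. The counts were 8 of 7485 in cone-like and 1867 of 17482 in Müller-like nuclei.

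**Figure D5:**
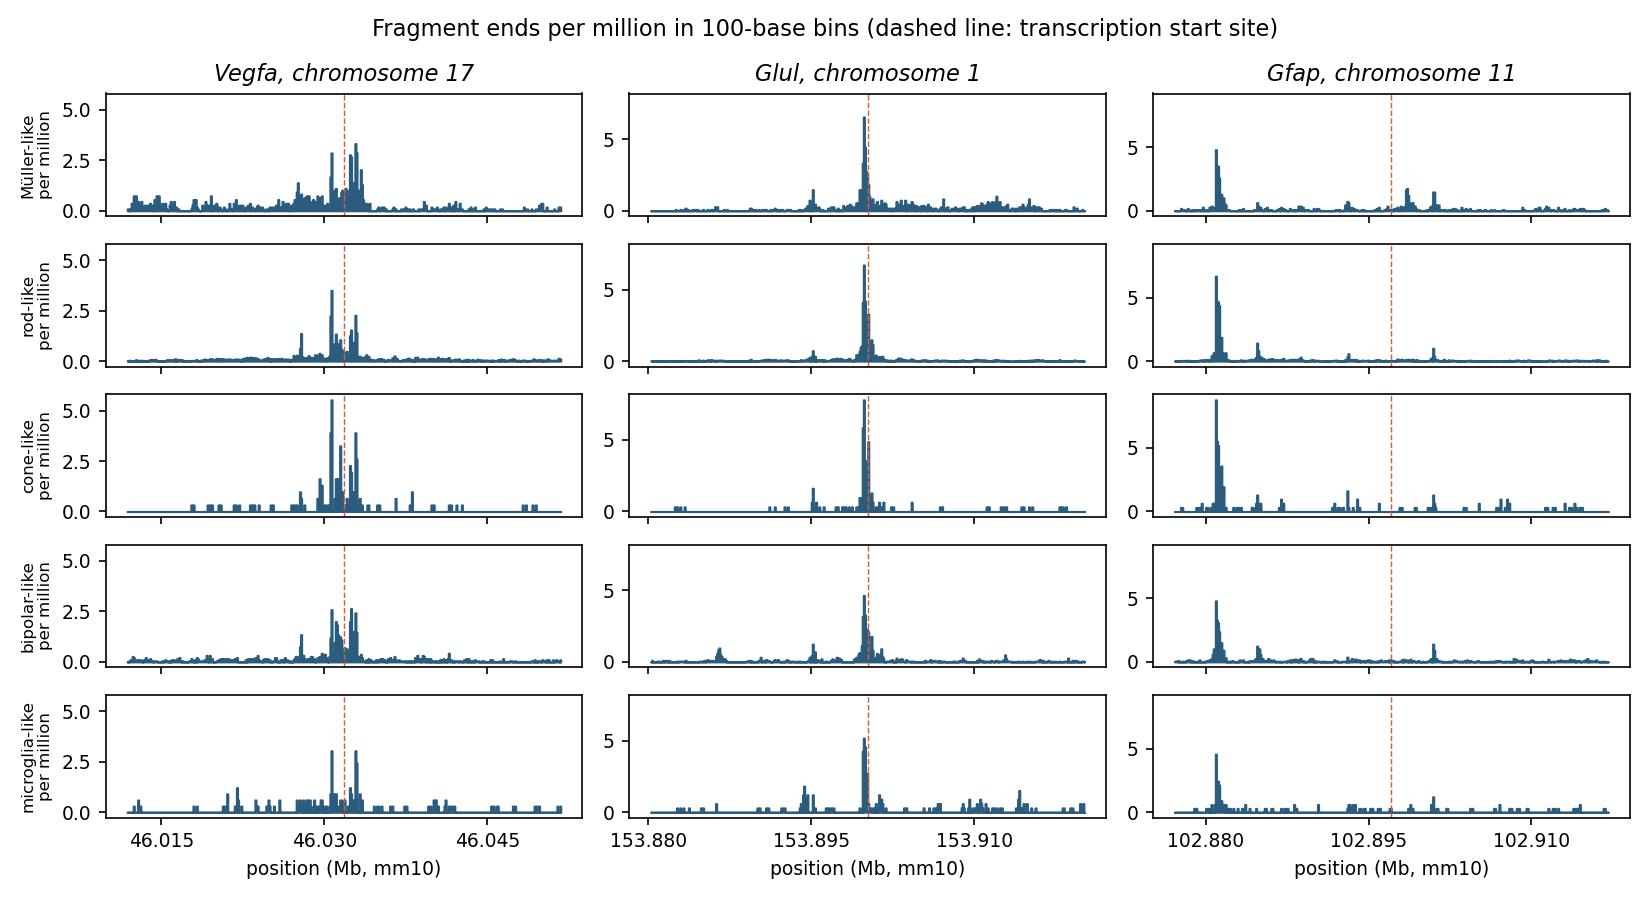
Lines show fragment ends in CPM in bins of 100 bases around Vegfa, Glul and Gfap in 5 classes, with the transcription start as a dashed line. At Gfap, Müller-like nuclei show signal upstream of the start that is low in the other classes drawn. The whole peaks counted for its promoter had 22.8 CPM in Müller-like nuclei against 2.58 in all others.

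Microglia-like and endothelial-like nuclei, the immune and vessel cells of the model, were compared with all other nuclei in the lists made for them. Ratios here add 1 count to each pool. In microglia-like nuclei, the 5 measured homeostatic genes had a median log2 ratio of 6.94 (6.06 to 7.27), with Siglech at 9.08, Sall1 at 6.94 and Cx3cr1 at 5.64. The activated list had 6.47 (5.71 to 6.98), with 9 of 9 members at least 2 times higher, led by the lipid receptor Trem2 (9.41), Lpl (8.29), Spp1 (7.39) and Cd68 (6.74). In the 11 endothelial-like nuclei, tip and tuft genes had a median of 7.37 (6.80 to 7.93), with Igfbp3 at 10.9, Cd34 at 8.55, the Tie2 ligand Angpt2 at 7.37 and Apln at 6.44. Barrier genes had 6.69 (5.99 to 7.56), with the tight junction gene Cldn5 at 10.7, Abcb1a at 9.50, Lef1 at 7.29 and the lipid transporter Mfsd2a at 6.69. Several of these genes also name their class.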

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

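All tests in this part were chosen after the results were seen, except the tests on nuclei sharing a barcode by sex and on a single animal, whose predictions were written first. The labels name 1 group, so no biological explanation was tested for any pattern.

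Outside the called barcodes, 31223845 fragments lay in 435388 other barcodes, a signal in data the comparisons did not use. Their enrichment at transcription starts was 6.78, against 26.1 in the kept nuclei. Among the 6852 kept nuclei, 233 (3.40%) held both Xist UMIs and Y fragments, where a nucleus of either sex should hold 1 of the 2. Female nuclei numbered 2030 and male nuclei 933, so the preparation held animals of both sexes.

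Photoreceptor and bipolar transcripts stood out in Müller subclusters 3 and 5. Free RNA brings no chromatin, but promoters of rod markers were 5.11 times as open in subcluster 3 as in subcluster 1 (4.28 to 6.16), which argues against free RNA as the whole cause. More than 1 nucleus under a barcode may account for it, since in nuclei with Xist the rate of Y fragments was 4.92 times that of subcluster 1 (2.31 to 12.5). That comparator was low: the rate was 46.3 CPM in subcluster 3, 63.6 in subcluster 5 and 10.2 in subcluster 1, but 39.3 in subcluster 2, 37.7 in rod-like and 38.1 in all kept nuclei, so the extent of sharing stays open. The deeper RNA of these subclusters also raises the chance that free Xist RNA marks a male nucleus, which this test does not separate.

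Gliosis, hypoxia and glycolysis transcripts stood out in Müller subcluster 4. RNA from astrocytes is argued against as the whole cause, since 20 astrocyte transcripts reached 0.106 (0.041 to 0.182) of the excess that the level of Gfap would need. They summed to 833 CPM, of which Cst3 alone gave 712, against 556 in subclusters 1 and 2 and 3176 needed. Lcn2, however, at 301 CPM in subcluster 4 and 4772 in astrocyte-like nuclei, was near the level that the 6.18% of astrocyte RNA needed for Gfap would bring. The interval leaves out the error of that share, which rests on few Gfap UMIs. Promoters of astrocyte markers, Gfap among them, had 62.9 CPM of peak counts (46.8 to 82.6) in subcluster 1 and 38.5 (25.6 to 55.6) in subcluster 2. They had 115 (73.8 to 171), on 24 counts, in subcluster 4. A part from astrocytes therefore stays open for subcluster 4. A single animal is argued against where animals differ in sex, since 54.2% of its sexed nuclei were female (32.8 to 74.4%), though a few animals of both sexes remain possible. Handling during digestion could not be excluded: immediate-early genes were higher by 0.63 on the log2 scale (0.43 to 0.82), which both handling and a state in the animal allow.

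RPE transcripts marked 109 nuclei of which 107 had rod chromatin. If an RPE nucleus shared each barcode, at least 50% of these nuclei were predicted to have at least 1.5 times the rod-like median of peak counts. The share was 36.7% (27.7 to 46.5%), under the prediction. This does not decide the question, since the prediction assumes how many peak counts an RPE nucleus adds, which was not measured. An earlier form of this test rested on an interval made from nuclei, pointed the same way and was replaced. The 5 RPE promoters had a median log2 ratio to other nuclei of 0.18 (-0.53 to 0.64), on few counts. The class held 21 nuclei without the highest 8% of Scrublet scores, but also 20 at a lower resolution. Signals of both sexes were seen in 2.75% of RPE-like nuclei (0.571 to 7.83%) and in 2.47% of rod-like nuclei. The rate of Y fragments in nuclei with Xist was 89.8 CPM (69.6 to 114) against 37.7 (35.1 to 40.5), from 37 nuclei of which 29 had 0 and 3 had at least 2. Sharing of barcodes stays open. Free RPE RNA spread evenly is argued against, since in the held-out UMIs, which did not name the nuclei, RPE markers were 195 times as high as in rod-like nuclei (167 to 229), while RPE RNA attached unevenly was not tested and stays open.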

How the results depend on the processing

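Of 142 values under alternatives, 92 of them planned, 73 stayed within the counting interval of the reported value, 68 moved outside it and 1 reversed. The reversed value was the angiogenic list in male nuclei, where 6 members were measured and the interval spanned 0 (-1.15 to 0.48). Shares, overlap and the 3 subcluster results cannot be negative by construction, so a sign could change in the other 4 results alone. Where no construction is named, the cause was not tested. Reported values were a Müller share of 4.51%, rod share 81.0%, Vegfa 4.36, angiogenic list 1.06, gliosis 1.42, hypoxia 0.47, homeostasis 1.30, promoters 1.34, overlap 93.3% and correlation 0.436. Looser filters gave Müller share 3.19%, rod share 67.5%, gliosis 0.61, hypoxia 0.21 and homeostasis 0.29. Stricter filters gave Müller share 6.34%, rod share 78.3% and angiogenic list 1.55. A lower resolution gave rod share 78.0%, angiogenic list 2.13, gliosis 0.95, homeostasis 0.67, promoters 1.47, overlap 90.6% and correlation 0.445. A higher resolution gave rod share 79.2%, gliosis 0.56 and homeostasis 0.46. With 3000 genes and 20 components came angiogenic list 2.52, hypoxia 0.63, homeostasis 1.97 and correlation 0.445. With all UMIs for both steps came rod share 82.0%, angiogenic list 0.59, homeostasis 1.17, promoters 1.5, overlap 94.4% and correlation 0.445. Exchanging the parts of the split gave angiogenic list 0.23. Keeping list and marker genes in the clustering gave gliosis 0.73, hypoxia 0.22 and homeostasis 0.57. Leaving out photoreceptor-led subclusters gave gliosis 0.50, hypoxia 0.13 and homeostasis 0.30. Gene bodies in place of promoters gave correlation 0.473. The other alternatives were chosen after seeing the data. No limit on peak counts gave Müller share 2.97%, rod share 86.0% and correlation 0.447. Removing the highest 8% of Scrublet scores gave Müller share 3.70%, rod share 78.5%, Vegfa 4.66, gliosis 0.25, hypoxia 0.0047, homeostasis 0.38, promoters 1.64 and overlap 95.2%. Removing nuclei with signals of both sexes gave rod share 82.3%, gliosis 0.83, hypoxia 0.21, promoters 1.66 and overlap 94.0%. Female nuclei alone gave Müller share 6.80%, rod share 72.2%, angiogenic list 0.19, promoters 1.67, overlap 89.8% and correlation 0.359. Male nuclei alone gave Müller share 6.86%, rod share 75.2%, Vegfa 4.66, angiogenic list -0.35, promoters 1.76 and correlation 0.310. Subclusters of at least 20 nuclei gave gliosis 2.10 and hypoxia 1.25. Those of at least 20 nuclei that were not photoreceptor-led gave gliosis 1.18, hypoxia 0.91 and homeostasis 0.84. Vegfa ranged from 4.22 to 4.66 over its 13 alternatives. The ranges of gliosis, hypoxia and homeostasis compare whichever subclusters were highest and lowest, so different settings compare different nuclei. A sex was found for 138 female and 64 male of 309 Müller-like nuclei but for 1466 and 702 of 5548 rod-like nuclei, which raises the Müller share in both sexes by construction. Single sexes and subclusters from chromatin gave no value for the 3 subcluster results, since under 2 subclusters of at least 50 nuclei were left. Motif shares were not run. Depth limits the classes of 15 and 11 nuclei, subcluster 4 with 36 nuclei, and genes under 20 UMIs. No paired analysis was possible because there was 1 sample of each kind and no second group.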

Other observations

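All values in this part concern genes or groups chosen after their values were seen, except the medians of the fixed lists. The 15 astrocyte-like nuclei had the highest gliosis median of the 7 classes compared with all other nuclei, rod-like nuclei not among them. It was a median log2 ratio to other nuclei of 3.82 (3.38 to 4.58), with 17 of 17 members at least 2 times higher. These ratios add 1 count to each pool, which is 17.4 CPM in the 57628 held-out UMIs of astrocyte-like nuclei. Members with few or no UMIs there can therefore read as at least 2 times higher. Among random lists matched on expression, which carry the same added count, the gliosis percentile was 100. The acute-phase gene Lcn2 was at 4772 CPM, against 40.2 CPM in Müller-like nuclei. Their transcripts also included the growth factor Igf2 (2065 CPM), the PDGF receptor Pdgfra (1510 CPM), Chil1 (3262 CPM) and the optic nerve factor Pax2 (729 CPM). Hypoxia targets had a median of -0.09 (-0.35 to 0.38) and glycolysis genes -0.51 (-1.02 to -0.36) there, and extracellular matrix genes 2.77 (2.25 to 3.39).

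Microglia-like nuclei had a JAK-STAT and interferon list median of 2.09 (1.57 to 2.76) and 10 of 12 members at least 2 times higher. Their cell cycle list had a median of 2.16 (1.20 to 2.78), with 5 of 8 at least 2 times higher, and the oxidative stress list 1.49 (1.00 to 1.88). The added count raises members with few UMIs in their 190178 held-out UMIs as well. The cell cycle median was also above 0 in endothelial-like (2.45), astrocyte-like (1.76) and RPE-like nuclei (1.23), and below 0 in cone-like and bipolar-like nuclei. Its percentile among matched random lists was 99.8 in microglia-like, 88.4 in endothelial-like, 87.9 in astrocyte-like and 99.5 in RPE-like nuclei. Endothelial-like nuclei had extracellular matrix genes at 3.10 (2.58 to 3.76), the Wnt and Norrin pathway at 3.51 (2.68 to 3.94) and secreted angiogenic factors at 3.64 (2.43 to 4.20). In their 40125 held-out UMIs 1 added count is 24.9 CPM, which raises members with few UMIs in these medians too. RPE-like nuclei had the retinoid list at 2.82 (2.49 to 3.11). Their transthyretin transcript Ttr was at 4738 CPM and the isomerase Rpe65 at 276 CPM, against 9.60 and 0.873 CPM in rod-like nuclei. Cone-like nuclei had glycolysis genes at 0.32 (0.08 to 0.46) and glial homeostasis at -2.89 (-3.19 to -2.37), and bipolar-like nuclei had NFI factors at 1.10 (0.93 to 1.26).

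The smallest Müller subcluster, of 6 nuclei, carried Crhbp at 2464 CPM, Optc at 1630 CPM, Reln at 4133 CPM and Aldh1a1 at 3716 CPM. Its Müller markers summed to 12512 CPM. Fibroblast markers summed to 607 CPM and ganglion markers to 379, against at most 22.2 and 43.3 in the other subclusters. Whether these nuclei are Müller cells was not tested. Promoters of the 8 leading genes of Müller subcluster 4 were together higher by 0.45 (0.16 to 0.73) on the log2 scale than in subclusters 1 and 2, but 6 of 8 single intervals spanned 0. Cdh13, at 2.60 (1.57 to 3.57), gave 17 of the 126 counts in subcluster 4 and 21 of the 682 in subclusters 1 and 2. Promoters of its gliosis genes had 557 CPM (460.3 to 668), beside 616 in subcluster 1 and 502 in subcluster 2.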
